A study of Mus musculus with 36 samples.

How the data were processed

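RNA of mouse embryos at embryonic day 15 was measured on 36 single-colour oligonucleotide arrays. The embryos carried 0, 1 or 2 copies of the megabladder (mgb) allele, and the labels give genotype, sex, tissue and an embryo number for each array. Per the labels' protocols, bladders were micro-dissected and snap frozen before RNA was taken with a spin-column kit, whole embryos were extracted in TRIzol, and biotin-labelled target was hybridised by the standard Affymetrix protocol. A custom array carried 30 of the samples, 24 bladders and 6 whole embryos. A genome-wide array carried 6 samples labelled whole embryo.

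The deposited values are log2 expression per probe set, made by the authors with a summarisation method and scaling that are not given in the sources used here. They were analysed as deposited, with no further background correction or scaling in the main analysis. Array medians were 4.31 to 4.57 on the genome-wide arrays, 5.46 to 5.94 on the bladder arrays, 6.49 to 6.55 on the custom arrays of female whole embryos and 6.79 to 6.86 on those of male whole embryos, so these sets appear on separate scales. On the custom arrays of whole embryos, 31% of probe sets held a single value on all 3 female arrays and 27.7% on all 3 male arrays. In all, 49.3% held a single value in at least 1 sex, against 0.3% with any value shared by 3 or more bladder arrays. Such collapsed values shrink the spread and hide genotype differences, and the step behind them is not given in the sources used here. No background or detection call was used, so dim probe sets carry values of unknown meaning, and the number of arrays limits the precision.

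Gene names, chromosomes and positions came from the authors' deposited annotation table, whose genome build is not given in the sources used here. Names were updated with the RefSeq gene table of GRCm38.p6, which was used for names only. Of 21303 distinct names, 12161 were current symbols, 6013 were updated through an older symbol and 113 through a transcript accession, while 3016 were kept as they stood. The custom array held 4019 probe sets, of which 64 were controls, 3774 had 1 gene name, 61 had several and 120 had none, and 3947 were shared with the genome-wide array. The genome-wide array held 45101 probe sets, of which 64 were controls, 39839 had 1 gene name, 636 had several and 4562 had none. Only probe sets with 1 name entered the gene tests, and each gene was represented by its probe set with the highest mean over the arrays of that type. This left 2183 genes on the custom array, 1406 on chromosome 11, 562 on chromosome 16 and 215 elsewhere or unplaced, and 20501 genes on the genome-wide array. The annotation file also held 6 columns of values named by embryo codes, which each fit more than 1 sample and were not used here.

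Groups, covariates, gene lists and the rule for named genes were fixed before the data were examined. Genotypes were compared with limma 3.58.1 in R 4.3.3, with linear models on the log2 values, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes of the array, at a threshold of 0.05. All arrays of a tissue and array type shared 1 estimate of the spread, and sex was a covariate. Tested were each pair of genotypes, a linear trend over mgb alleles in bladder, sex, the interaction of sex and genotype, bladder against whole embryo on the custom array, and the interaction of tissue and genotype. All adjusted p-values of single genes come from these limma models. Animals are told apart by embryo number, but litters are not named, so p-values measure the spread between embryos. The bladder numbers fall into 3 ranges, which were treated as possible batches.

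The 31 gene lists were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, and again with the correlation estimated from the data. Members of smaller lists are given without a set test. Neighbouring genes were searched for runs of higher values, scored as the sum of the log2 differences less 0.3 each, with 1000 shuffles of gene positions. The permutation p of a run measures how closely high values sit together and not the spread between embryos. Named genes are Myocd, the up to 10 largest rises and 10 largest falls past the threshold, and the up to 4 members with the smallest p of each described list or run; for sex they are the sex-linked genes. Genes named outside this rule are said to be so.

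The models were tested on simulated data with 200 changed genes. In the homozygous bladder comparison 38.8% of genes changed by 0.5 on the log2 scale were called, 77.6% of those changed by 1 and 100% of those changed by 2. For heterozygous bladders the shares were 14.9%, 61.2% and 98.5%, and for the custom arrays of whole embryos 38.8%, 61.2% and 84.8%. The simulated whole embryos kept the small spread of collapsed probe sets but not the loss of genotype differences there. Their shares therefore do not measure what the real arrays of whole embryos can detect. On the genome-wide arrays, with 2 samples per genotype, 0% were called at any of these sizes. The 200 changed genes stood among 20501 there and among 2183 on the custom array. The adjustment over all genes depends on how many of them change, so the shares cannot be compared between array types. Nor do they hold where fewer genes change. Noise was drawn independently for each gene, without the ranges of embryo numbers. Alternatives were quantile normalization, median centring, a filter on the median level, every probe set on its own, limma with an intensity trend and robust moderation, models without sex or with only the 2 groups compared, collection ranges as a block or analysed alone, each sex alone, and removal of each array in turn. A block of 3 ranges and the removal of collapsed values were added after the data were seen. The counts of called genes were also set against 100 splits of the arrays, the real split included, and, added after the data were seen, those between bladder genotypes against 100 splits within the 3 ranges.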

Results

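The series profiled mouse embryos at embryonic day 15 that were wild type, heterozygous or homozygous for megabladder (mgb), a transgene-insertion allele whose homozygotes form a dilated bladder with little detrusor smooth muscle. Bladders were measured on a custom array made mostly of genes on chromosomes 11 and 16, with 11 homozygous (7 female, 4 male), 7 heterozygous (3 female, 4 male) and 6 wild-type (3 female, 3 male) embryos. On the same array 6 whole embryos were measured, and 6 further samples labelled whole embryo were run on a genome-wide array, each with 1 female and 1 male per genotype. Replicates were separate embryos and none was a repeat of another in its group. The closest pair within a group, among homozygous bladders, differed by a median of 0.183 on the log2 scale, and at most 0.228% of values were identical. Only pairs of the same tissue set and genotype were compared. In the sets labelled whole embryo such a pair is 1 female and 1 male, so the values shared within a sex do not show there. By embryo number the bladder arrays fell into 3 ranges of 7, 8 and 9 arrays, with array medians of 5.83 to 5.94, 5.76 to 5.86 and 5.46 to 5.61. Each range held all genotypes, with 1, 3 and 2 wild-type and 4, 2 and 5 homozygous embryos. For the bladder genes named as passing between genotypes, values within ranges are given beside the pooled ones, with the first pair of ranges joined as the lower ranges and the last as the higher range.

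The sex labels were checked on the genome-wide arrays. Xist, the RNA of the inactive X chromosome, lay between 8.35 and 9.69 on the log2 scale in females and between 2.17 and 3.16 in males. Y-linked Ddx3y lay at 2.71 to 3.62 in females and 9.80 to 9.96 in males, and Eif2s3y and Uty were separated in the same way. Kdm5d overlapped between the sexes, at 4.27 to 4.72 and 4.39 to 5.50, as did Tsix, at 2.15 to 2.54 in females and 2.37 to 3.77 in males. These genes could not be read on the custom array, where sex labels were taken as given.

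The 6 genome-wide arrays labelled whole embryo resembled the bladder arrays more than the whole embryos on the custom array. Across shared probe sets, which are not independent replicates, the lowest correlation of each with any bladder was 0.864 to 0.902, and the highest with any of the other whole embryos was 0.789 to 0.820. Myocd, a transcriptional coactivator that drives smooth muscle genes, lay at 10.6 to 11.98 on these arrays, against a mean of 11.40 in bladders and 5.66 in whole embryos on the custom array. Hba-x, an embryonic globin, lay at 4.86 to 6.29 on these arrays, against means of 8.16 and 12.16. Among genes chosen after their values were seen, the uroplakin gene Upk1a lay at 7.40 to 8.07 on 5 arrays and at 4.02 on the heterozygous male array. These samples are therefore called the arrays labelled whole embryo, and their tissue is in doubt.

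**Figure D1:**
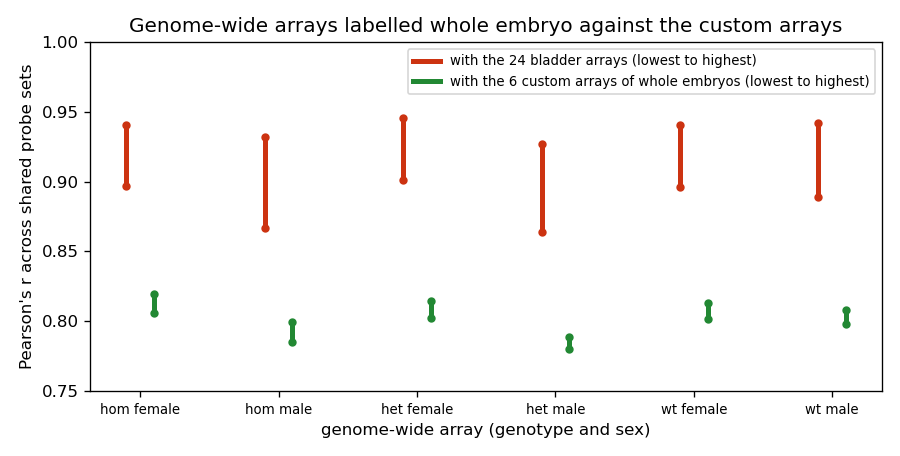
Lowest to highest Pearson correlation across shared probe sets of each of the 6 genome-wide arrays (x axis, genotype and sex) with the 24 bladder arrays (red) and with the 6 custom arrays of whole embryos (green). Correlations with bladders begin at 0.864, and those with whole embryos end at 0.820.

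Homozygous bladders had lower levels of smooth muscle genes than wild-type bladders. Myh11, the smooth muscle myosin heavy chain, fell by 2.38 on the log2 scale (SE 0.33, adjusted p = 5.69e-05), from 11.26 ± 0.27 (SD, n = 6) to 8.91 ± 0.73 (n = 11), a fold of 5.19. Kcnmb1, a subunit of the calcium-activated potassium channel of smooth muscle, fell by 2.54 (SE 0.34, adjusted p = 4.98e-05), and the myosin light chain kinase Mylk fell by 0.64 (SE 0.12, adjusted p = 0.002). Smtn, which binds actin in smooth muscle, differed by -1.26 (SE 0.37, adjusted p = 0.0749). Mylk did not pass in the higher range (0.137), in females (0.162) or in males (0.42) alone, nor Kcnmb1 in females (0.105). The lower and higher ranges gave -2.11 and -2.81 for Myh11, -2.25 and -2.77 for Kcnmb1, -0.76 and -0.62 for Mylk and -0.94 and -1.45 for Smtn. Of the 4 contractile genes measured, 3 fell over all genes and 4 adjusted over the list alone. Their median difference was -1.82, with -1.77 under a block of 3 ranges, -1.53 in the lower ranges and -2.11 in the higher range.

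Myocd itself fell by 1.48 (SE 0.39, adjusted p = 0.041), from 12.22 ± 0.19 in 6 wild-type to 10.73 ± 1.02 in 11 homozygous bladders, and all 11 homozygous arrays lay below every wild-type array. The difference was -2.33 in the lower ranges and -0.79 in the higher range, and -1.27 (adjusted p = 0.0018) with 3 ranges as a block. Its call was lost with median centring (adjusted p = 0.07), in a model of only the 2 groups (0.0864), in each sex alone and in the higher range alone. It was also lost without any 1 of 12 arrays, namely homozygous replicates 1, 2, 3 and 8, heterozygous replicates 1 and 2 and each of the 6 wild-type arrays, where the difference stayed between -1.53 and -1.29 and the adjusted p reached 0.119. Among the other regulators of smooth muscle measured, Hand1 differed by 1.25 (adjusted p = 0.0749), Meis1 by -0.08 and Mrtfb by -0.16. Adjusted over the list alone, Myocd included, 1 rose, Hand1, and 1 fell, Myocd.

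The largest falls were not limited to smooth muscle markers. Sh3bgr had the largest, -3.70 (SE 0.34, adjusted p = 3.34e-07), from 9.62 ± 0.69 to 5.95 ± 0.82. Popdc2, a membrane protein of muscle cells, fell by 3.35 (SE 0.50), the amine oxidase Aoc3 by 2.67 (SE 0.26), the cation channel Trpv2 by 2.63 (SE 0.38) and the glucose transporter Slc2a4 by 1.55 (SE 0.23). Striated muscle myosin light chains also fell, Myl4 by 2.64 (SE 0.36) and Myl7 by 2.35 (SE 0.31), with adjusted p at most 1.21e-04 in this group of 7 genes. For each of these genes all 11 homozygous arrays lay below every wild-type array, and each call was kept in all 24 removals of a single array. In the higher range alone Popdc2 (adjusted p = 0.0572) and Myl7 (0.117) did not pass, nor did Popdc2 (0.0694) and Trpv2 (0.139) in females alone or Popdc2 (0.0636), Myl4 (0.151), Myl7 (0.0713) and Slc2a4 (0.197) in males alone. Within the lower and the higher ranges the differences were -3.33 and -4.15 for Sh3bgr, -2.72 and -4.07 for Popdc2, -2.81 and -2.86 for Aoc3, -2.32 and -2.97 for Trpv2, -1.62 and -1.62 for Slc2a4, -2.65 and -2.60 for Myl4 and -2.27 and -2.47 for Myl7. Of 3 skeletal muscle genes Myl4 alone fell, and the list's median was -0.28 with a mean of -1.04. Of 4 proliferation genes the mitotic kinase Aurkb fell, by 0.55 (SE 0.13, adjusted p = 0.0256); 2 fell adjusted over the list alone, with Birc5 at -0.33. Aurkb no longer passed without wild-type replicate 1 (adjusted p = 0.0795), 2 (0.0689), 4 (0.06), 5 (0.0513) or 6 (0.0559), in a model of only the 2 groups (0.0556), or in the lower ranges (-0.46), the higher range (-0.73) or either sex alone (0.0987 to 0.509).

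**Figure D2:**
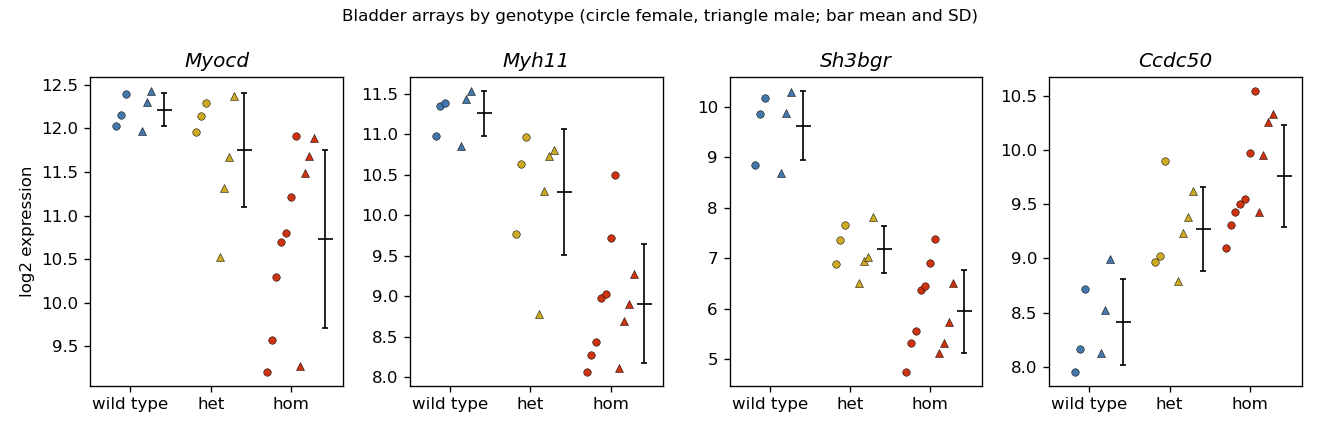
Log2 expression (y axis) of Myocd, Myh11, Sh3bgr and Ccdc50 in each bladder array by genotype (x axis; wild type n = 6, heterozygous n = 7, homozygous n = 11), with circles for females, triangles for males and bars for mean and SD. Homozygous arrays lie below all wild-type arrays for the first 3 genes and above them for Ccdc50, whose means are 8.41, 9.27 and 9.76.

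Among the rises, Gabrb2, a subunit of the GABA-A receptor, rose by 1.72 (SE 0.21, adjusted p = 1.20e-05), from 5.38 ± 0.80 to 7.17 ± 0.29, and lay above every wild-type array in 11 of 11 homozygous bladders. Ccdc50 rose by 1.38 (SE 0.21, adjusted p = 2.22e-04), also in 11 of 11. The homeobox gene Hoxb3 rose by 1.39 (SE 0.28, adjusted p = 0.0058) and the peptide transporter Slc15a2 by 1.20 (SE 0.23, adjusted p = 0.003). These 4 calls were kept without any single array. The histone gene H2bu2 rose by 1.72 (SE 0.42), the homeobox gene Dlx3 by 1.57 (SE 0.39), the collagen gene Col8a1 by 1.32 (SE 0.33), the transcriptional repressor Bcl6 by 1.28 (SE 0.31), Etv4, an ETS factor that responds to fibroblast growth factor, by 1.12 (SE 0.26) and Parp9 by 1.06 (SE 0.28), with adjusted p of 0.0208 to 0.0403. Each of these 6 lost its call without wild-type replicate 1 and without replicate 2. So did Dlx3, Col8a1, Bcl6 and Parp9 without replicate 4, H2bu2, Dlx3 and Etv4 without replicate 5, H2bu2, Dlx3, Col8a1 and Bcl6 without replicate 6, and Parp9 without heterozygous replicate 1 or homozygous replicates 1, 2, 4, 8, 9 or 11, with adjusted p of at most 0.118 for H2bu2, 0.0904 for Dlx3 and Etv4, 0.124 for Col8a1, 0.086 for Bcl6 and 0.158 for Parp9. With 3 ranges as a block Dlx3 (adjusted p = 0.0745), Col8a1 (0.0599) and Parp9 (0.0789) no longer passed, and median centring ended the calls of Col8a1 (0.0551) and Parp9 (0.0626). A model of only the 2 groups ended those of H2bu2 (0.0536) and Parp9 (0.0671), and Parp9 also missed the threshold with quantile normalization (0.0588) and without sex in the model (0.06). The lower and higher ranges gave 1.70 and 1.82 for Gabrb2, 1.25 and 1.36 for Ccdc50, 2.10 and 0.58 for Hoxb3, 1.41 and 0.96 for Slc15a2, 2.47 and 1.04 for H2bu2, 2.15 and 1.19 for Dlx3, 1.72 and 0.86 for Col8a1, 2.01 and 0.80 for Bcl6, 1.89 and 0.25 for Etv4 and 1.63 and 0.35 for Parp9. In the higher range alone Ccdc50 passed and the 9 others did not, with adjusted p from 0.151 for Gabrb2 to 0.898 for Hoxb3, 0.919 for Parp9 and 0.94 for Etv4. In females alone Gabrb2, Bcl6 and Etv4 passed, and in males alone Gabrb2.

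Genes of the urothelium, the epithelium lining the bladder, were higher in homozygotes for 6 of 6 members measured, with a median of 0.58 and a mean of 0.71. The list passed camera (adjusted p = 0.0087, and 0.0226 with 3 ranges as a block), but not with the correlation estimated from the data (adjusted p = 0.191 with an estimated correlation). None passed over all genes and 1 rose adjusted over the list alone: Cldn7, a tight junction protein, differed by 1.23 (SE 0.42, adjusted p = 0.143), Krt20 by 0.96, the uroplakin Upk1b by 0.57 and Krt19 by 0.41. The median was 0.67 with the block, 0.82 in the lower ranges and 0.30 in the higher range. Extracellular matrix genes (5 measured, median 0.11, camera adjusted p = 0.0995) and fibroblast and insulin-like growth factor genes (6 measured, median 0.15, adjusted p = 0.0995) did not pass as lists; adjusted over the list alone 1 of each rose, Mfap4 at 0.48 and Etv4. Lists too small for a set test held Lhx1 at 1.33 (adjusted p = 0.123) and Wnt9b at 1.20 (0.240), both of nephric duct development, and the neuronal genes Gap43 at 1.31 (0.240) and Mapt at 1.17 (0.107). Red cell genes had a median of 0.21, with 0 of 3 past the threshold by limma, and the liver gene Ahsg differed by -0.76.

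In all, 55 of 2183 genes passed between homozygous and wild-type bladders, 19 higher and 36 lower, and 264 had an unadjusted p under 0.05 where chance would give 109. Of the 55 genes 10 rose and 15 fell by over 2-fold. With 3 ranges as a block 49 of the 55 passed, and their sign was kept in 55 within the lower ranges and in 54 within the higher range. The count fell to 29 without wild-type replicate 1, 28 without replicate 2, 33 without replicate 5 and 35 without replicate 6. It was 111 in the lower ranges alone and 10 in the higher range alone, and 95 with the 2 ranges as a block.

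Heterozygous bladders differed from wild type in 2 genes, both lower. Myl4 fell by 2.49 (SE 0.40, adjusted p = 0.0022), from 11.53 ± 0.56 (n = 6) to 9.03 ± 0.84 (n = 7), and Sh3bgr fell by 2.43 (SE 0.37, adjusted p = 0.0022), to 7.18 ± 0.46. Sh3bgr lay below every wild-type array in 7 of 7 heterozygotes and Myl4 in 6. With 3 ranges as a block the values were -2.45 and -2.44, and within the lower and higher ranges they were -2.29 and -3.01 for Myl4 and -2.45 and -2.40 for Sh3bgr. Sh3bgr passed in the lower ranges alone, but not in the higher range (0.148), in females (0.686) or in males (0.328), and Myl4 in none of these parts (0.207 to 0.897). Myocd differed by -0.47 (SE 0.43, adjusted p = 1.00). Of the contractile genes 0 of 4 passed limma's test over all genes and 3 fell adjusted over the list alone, with a median of -0.71. Over all genes 93 had an unadjusted p under 0.05. With 3 ranges as a block 10 genes passed, among them Ccdc50 (0.90, adjusted p = 1.72e-04), Aoc3 (-1.24, 0.0365), Myl7 (-1.47, 0.0395) and D16Bwg1543e (0.69, 0.0171). Besides Myl4 and Sh3bgr, genes chosen after their values were seen passed without single arrays: Aoc3 and Ifi35 without homozygous replicate 4 (count 4), Igsf11 and Myl7 without homozygous replicate 6 (count 4), Ifi35 without wild-type replicate 3 (count 3), and Aoc3, Gip and Myl7 without wild-type replicate 4 (count 5).

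Homozygous bladders differed from heterozygous ones in 4 genes, each with an adjusted p of 0.0168. Gabrb2 rose by 1.05 (SE 0.20), while Kcnmb1 fell by 1.69 (SE 0.33), Aoc3 by 1.38 (SE 0.25) and Slfn5, of the Schlafen family, by 1.13 (SE 0.22). The lower and higher ranges gave 0.92 and 1.46, -1.34 and -1.99, -1.64 and -1.43, and -1.28 and -0.62 in that order, and all 4 passed with the block of 3 ranges (adjusted p of 0.0236 to 0.0282). Aoc3 and Slfn5 passed in the lower ranges alone and Kcnmb1 in males alone; in the other parts by range or sex none of the 4 passed (0.0816 to 0.911). Without heterozygous replicate 1 or 2 the count was 0 (smallest adjusted p by limma 0.0836 and 0.0634), and without replicate 5 it was 2, Gabrb2 and Aoc3. Kcnmb1 also missed the threshold without homozygous replicate 11 (adjusted p = 0.0507) or heterozygous replicate 6 (0.0608). Slfn5 was dim, at 3.56 ± 0.58 in wild-type, 4.25 ± 0.53 in heterozygous and 3.09 ± 0.29 in homozygous bladders. Its heterozygous mean thus lay above both others, and homozygotes differed from wild type by -0.45 (adjusted p = 0.438). Myocd differed by -1.01 (SE 0.38, adjusted p = 0.605). At an unadjusted p under 0.05 there were 130 genes.

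A linear trend over the number of mgb alleles passed for 61 genes, 23 rising and 38 falling, and 54 of these were among the 55 above, from the same arrays. The count was 37 without wild-type replicate 1, 33 without replicate 2 and 120 with the 2 ranges as a block. Pooled over the ranges, the heterozygous mean of 54 of the 55 genes lay between the means of the other genotypes. In 20 simulations with heterozygotes set equal to wild type, a median of 59.8% and at most 70.7% of called genes did so. The simulations drew independent noise for each gene. Called genes that move together would widen the spread of this share, so it cannot exclude heterozygotes like wild type. In the higher range alone, with 2 wild-type and 2 heterozygous arrays, some of the 10 largest rises and 10 largest falls departed from this order. Heterozygous and homozygous differences from wild type were -0.59 and 1.19 for Dlx3, -0.03 and 0.58 for Hoxb3, -0.14 and 0.25 for Etv4 and 0.46 and 0.35 for Parp9. They were -3.01 and -2.60 for Myl4 and 0.04 and -0.79 for Myocd, and the others kept the order. A departure of heterozygotes from the midpoint passed limma's test in 0 genes, with 46 at an unadjusted p under 0.05 and a smallest adjusted p of 0.336.

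Female and male bladders differed in 0 of 2183 genes by limma, with 79 at an unadjusted p under 0.05, fewer than the 109 of chance. The effect of genotype differed between the sexes in 0 genes, with 51 at an unadjusted p under 0.05. The latter count was 4 without wild-type replicate 6, namely Atp10b, Kcnj15, Cldn8 and Abcc3, chosen after their values were seen. The sex-linked genes fixed for this comparison were not on the custom array.

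The calls between homozygous and wild-type bladders were spread over the chromosomes that the custom array covers. On chromosome 11, 2.20% of genes passed (10 higher, 21 lower), and on chromosome 16, 3.56% (9 higher, 11 lower), a difference within chance (Fisher's exact test, 2-sided p = 0.115). No chromosome passed camera as a whole, with a smallest adjusted p of 0.0616. The highest scoring run of neighbouring genes was in the Hoxb cluster of homeobox genes on chromosome 11, from position 96015409 to 96173888 in the deposited annotation. It held Hoxb13, Hoxb7, Hoxb5os, Hoxb6, Hoxb5, Hoxb4, Hoxb3 and Hoxb2, the 8 measured genes there, with a mean difference of 0.90 and 7 of 8 higher (permutation p = 0.001, the smallest that 1000 shuffles allow). Hoxb3 passed on its own, and Hoxb2 differed by 0.65 (SE 0.20, adjusted p = 0.0919), the antisense gene Hoxb5os by 2.13 (SE 0.67, adjusted p = 0.106) and Hoxb6 by 0.78 (SE 0.34, adjusted p = 0.325). Probe sets cannot be assumed to tell overlapping antisense transcripts apart. The run's mean was 0.73 with 3 ranges as a block (permutation p = 0.004) and 1.497 in the lower ranges (0.001), but 0.34 in the higher range (permutation p = 1). Among probe sets above the median level this run was not found on chromosome 11, where the best score was Dlx3 alone (permutation p = 0.995); there a run of 10 genes from St6gal1 to D16Bwg1543e on chromosome 16 had a mean of 0.59 (permutation p = 0.006). Over all genes the best run on chromosome 16 was 6 genes from St6gal1 to Bcl6, short of D16Bwg1543e, and did not pass (mean 0.69, permutation p = 0.400), nor did those at the other score offsets (0.391 and 0.447).

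**Figure D3:**
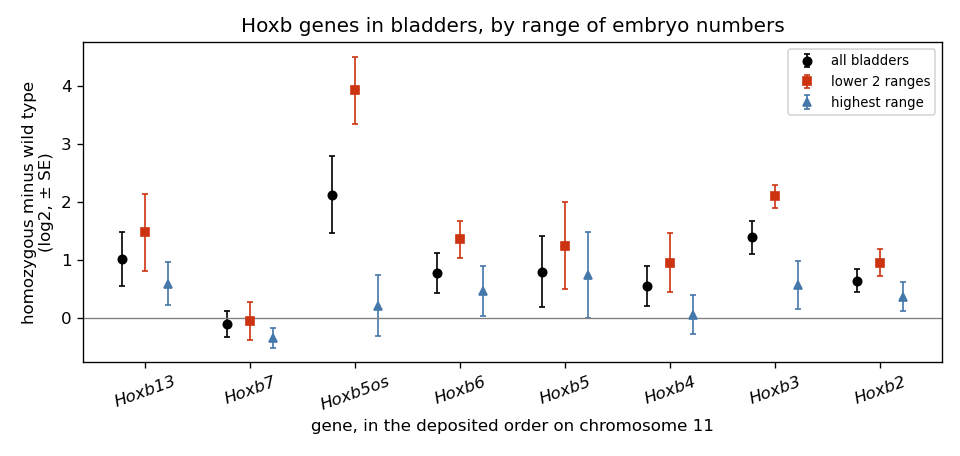
Homozygous minus wild-type difference (log2, ± SE) of the 8 Hoxb genes of the run, in their deposited order, for all bladders (black), the lower ranges of embryo numbers (red) and the highest range (blue). The mean is 0.90 in all bladders, 1.497 in the lower ranges and 0.34 in the highest range.

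Ccdc50 and its neighbour D16Bwg1543e on chromosome 16, each read from its brightest probe set, had higher means with more mgb alleles on all array sets. In bladder D16Bwg1543e (position 26233287) rose by 0.85 (SE 0.17, adjusted p = 0.0058), and Ccdc50 (position 26173527) by the 1.38 given above. In heterozygous bladders Ccdc50 lay 0.84 and D16Bwg1543e 0.64 above wild type (adjusted p = 0.391 and 0.521). Between homozygotes and heterozygotes they differed by 0.54 and 0.21 (adjusted p = 0.643 and 0.997), so a step from 1 to 2 alleles was not shown. Of the other Ccdc50 probe sets, tested on their own, the one at position 26173447 rose by 1.09 (adjusted p = 6.63e-05), while another differed by 0.63 (adjusted p = 0.66) and, against the order by alleles, by 0.98 in heterozygotes (adjusted p = 0.999). On the arrays labelled whole embryo Ccdc50 and D16Bwg1543e differed by 1.62 and 1.22 in homozygotes (adjusted p = 0.558 and 0.606). In heterozygotes there they differed by 1.08 and 0.68 (adjusted p = 0.793 and 0.873). In whole embryos on the custom array the homozygous differences were 1.52 and 1.46 (adjusted p = 0.330 and 0.524), and this pair was the best run (mean 1.49, permutation p = 0.002). There both passed with median centring (adjusted p = 0.0164 and 0.0365). The permutation there shuffled many differences that collapsed values hide, and it does not measure the spread between embryos. Its p therefore cannot show how far the pair stands out. In bladder D16Bwg1543e lost its call with median centring (adjusted p = 0.062), and the lower and higher ranges gave 0.65 and 0.90, where it did not pass (0.0655 and 0.137). In females and males alone neither D16Bwg1543e (0.139 and 0.404) nor Ccdc50 (0.0934 and 0.0803) passed. On the arrays labelled whole embryo the best run on chromosome 16 was wider, 28 genes from Ahsg to Fgf12 around this pair (mean 0.48, permutation p = 0.0599); with a lower score offset it was 32 genes from C79999 to Fgf12 (mean 0.44, permutation p = 0.006). With a higher offset or among probe sets above the median level the best run lay elsewhere, from Usp25 (permutation p = 1 for each). Neighbouring probe sets within 1100000 positions, 13 in number and mostly dim, had a median difference of -0.04 in bladder.

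**Figure D4:**
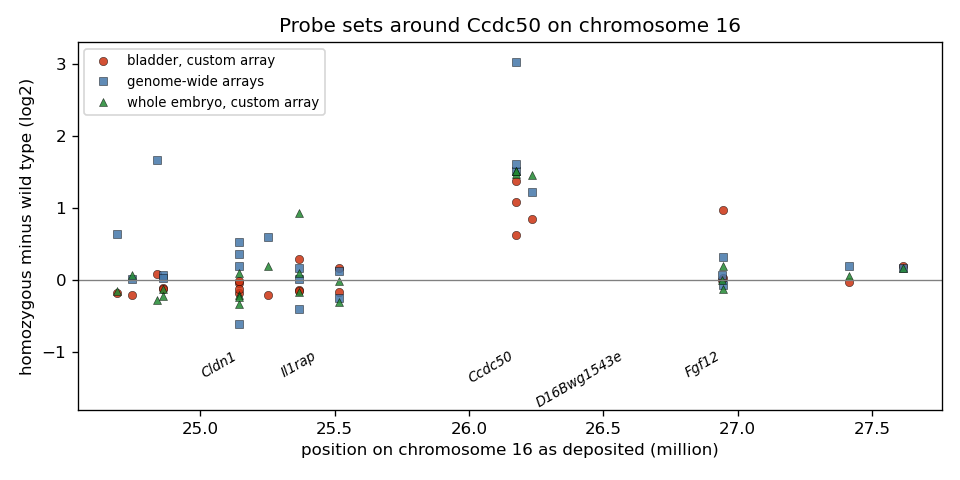
Homozygous minus wild-type difference (log2, y axis) of each probe set by its deposited position on chromosome 16 (x axis), in bladders (circles), the genome-wide arrays labelled whole embryo (squares) and whole embryos on the custom array (triangles). The probe sets of Ccdc50 and D16Bwg1543e lie at 0.63 or above in all 3 sets, and the median of the 13 neighbours in bladder is -0.04.

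On the arrays labelled whole embryo, homozygotes had lower smooth muscle contractile genes than wild type, by a median of -1.48 with 28 of 28 members lower (camera adjusted p = 6.10e-32; adjusted p = 0.382 with an estimated correlation). Lmod1, an actin nucleator of smooth muscle, differed by -3.87 (SE 0.35, adjusted p = 0.0741), Myh11 by -3.17 (SE 0.39), the Z-disc protein gene Ldb3 by -2.73 (SE 0.33) and Kcnmb1 by -2.19 (SE 0.34), and adjusted over the list alone 19 fell. Myocd differed by -0.86 (SE 0.30, adjusted p = 0.738). Cardiac muscle genes had a median of -0.32 and a mean of -1.12 (adjusted p = 2.14e-05; adjusted p = 0.382 with an estimated correlation; 3 fell adjusted over the list alone), with the sarcoplasmic reticulum protein gene Pln at -4.30, the troponin gene Tnnt2 at -4.17 and Myl7 at -2.28. Skeletal muscle genes had a median of -0.23 (adjusted p = 0.0121; adjusted p = 0.639 with an estimated correlation; 4 fell adjusted over the list alone), with Acta1 at -2.47. The cardiac median was -0.55 without homozygous replicate 2, -0.78 without wild-type replicate 2 and -0.13 without wild-type replicate 1, where the list no longer passed (adjusted p = 0.501). The skeletal median lay between -0.59 and 0.03 over removals of 1 array, and the list no longer passed without homozygous replicate 2 (adjusted p = 0.276) or wild-type replicate 1 (adjusted p = 0.976).

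Liver genes were higher in the same homozygotes by a median of 1.31 (camera adjusted p = 2.09e-05; adjusted p = 0.427 with an estimated correlation), and 5 of 11 rose adjusted over the list alone. Fga differed by 3.35 (SE 0.73), Alb, which encodes albumin, by 3.13 (SE 0.92), Apoa2 by 2.96 (SE 0.78) and Fgg by 1.33 (SE 0.41). Red cell genes had a median of 0.44 (adjusted p = 2.12e-04; adjusted p = 0.382 with an estimated correlation; 1 rose adjusted over the list alone), with Rhag at 1.65 and Slc4a1 at 1.15. The best runs of neighbouring genes held these liver genes, D5Wsu152e, Alb and Afp on chromosome 5 (mean 2.73, permutation p = 0.001, the smallest possible) and D3Ertd508e to Fgb on chromosome 3 (5 genes, mean 1.51, permutation p = 0.003, and 0.046 with a lower score offset). Among probe sets above the median level the run on chromosome 5 was Alb and Afp (mean 3.48, permutation p = 0.001), while that on chromosome 3 was not found, the best there being S100a8 and S100a9 (permutation p = 1). Proliferation genes were lower for 29 of 30 members (median -0.30, adjusted p = 2.12e-04; 0.637 with an estimated correlation), with Foxm1 at -0.96, and oxidative phosphorylation genes for 21 of 21 (median -0.31, adjusted p = 4.08e-04; 0.626). Genital and sex hormone genes had a median of 0.30 (adjusted p = 8.21e-04; 0.382 with an estimated correlation), with Emx2 at 3.10 and the receptor gene Esr1 at 1.26. Wnt (0.26, adjusted p = 0.0063), hedgehog (0.26, 0.0188), cartilage and bone (0.40, 0.0261), retinoid (0.27, 0.027) and TGF-beta and BMP (0.19, 0.0427) lists also passed with positive medians. With an estimated correlation these 5 had an adjusted p = 0.382, and 0 of the 13 lists passed camera. The liver median was 0.83 without homozygous replicate 1 and 0.82 without wild-type replicate 2, and the genital median was 0.49 without homozygous replicate 2. The medians of proliferation and oxidative phosphorylation genes were -0.52 and -0.48 without wild-type replicate 1. Without wild-type replicate 2 they were -0.12 and -0.13 and neither list passed (adjusted p = 0.254 and 0.116). That removal also ended the calls of the genital (0.115), Wnt (0.174), hedgehog (0.115), cartilage and bone (0.387), retinoid (0.307) and TGF-beta and BMP (0.348) lists, the median of the cartilage list being 0.26. Without homozygous replicate 1 cartilage and bone (0.116), hedgehog (0.0617), retinoid (0.229) and TGF-beta and BMP (0.421, median 0.09) did not pass, and the Wnt median was 0.15. Without homozygous replicate 2 oxidative phosphorylation (0.126), hedgehog (0.268), TGF-beta and BMP (0.126) and Wnt (0.0836) did not pass, and the retinoid median was 0.44. Without wild-type replicate 1 hedgehog (0.0986), retinoid (0.0505) and TGF-beta and BMP (0.052) did not pass, and without either heterozygous array TGF-beta and BMP did not (0.0846).

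Heterozygotes on the arrays labelled whole embryo had lower skeletal muscle genes, by a median of -1.16 (camera adjusted p = 2.20e-14; adjusted p = 0.556 with an estimated correlation; 12 of 23 fell adjusted over the list alone), with Acta1, skeletal actin, at -4.04 (SE 0.40), Myl4 at -3.46 and the troponin genes Tnnc2 at -2.57 and Tnnc1 at -2.06. Nerve and neural crest genes had a median of -0.98 (adjusted p = 9.77e-14; adjusted p = 0.556 with an estimated correlation; 5 fell adjusted over the list alone), with Elavl4 at -2.10. Smooth muscle contractile genes were lower for 28 of 28 members (median -0.62, adjusted p = 3.18e-12; adjusted p = 0.556 with an estimated correlation; 4 fell adjusted over the list alone), with Des at -2.51 and Ldb3 at -1.98. Urothelium genes were lower for 26 of 29 (median -0.82, adjusted p = 5.53e-11; adjusted p = 0.556 with an estimated correlation; 3 fell adjusted over the list alone), with Krt15 at -2.07, Krt5 at -2.50 and Trp63 at -1.41. That median was -0.16 without the male array, heterozygous replicate 2, which had Upk1a at 4.02, and -1.48 without replicate 1. Endothelium (0.41, adjusted p = 0.0046), extracellular matrix (0.22, 0.0039), cardiac muscle (-0.38, 0.0195), oxidative phosphorylation (-0.22, 0.0163), red cell (0.15, 0.0457) and TGF-beta and BMP (0.14, 0.0457) lists also passed. Of these 10 lists 0 passed camera with an estimated correlation, at adjusted p = 0.556 or, for oxidative phosphorylation, 0.767. The skeletal median was -0.59 and -1.803 without heterozygous replicates 1 and 2 and -0.67 without wild-type replicate 1, and the nerve median was -0.42 without heterozygous replicate 1. The contractile median was -0.93 and -0.33 without wild-type replicates 1 and 2, and the urothelium median -0.53 without wild-type replicate 2. Without heterozygous replicate 1 the calls of cardiac muscle (adjusted p = 0.434, median -0.15), endothelium (0.404, median 0.21), extracellular matrix (0.199), red cell (0.191), oxidative phosphorylation (0.106) and TGF-beta and BMP (0.0856, median 0.24) lists ended. Without wild-type replicate 1 those of cardiac muscle (0.774, median 0.04), endothelium (0.136), extracellular matrix (0.0909, median 0.13) and TGF-beta and BMP (0.0518, median 0.26) ended, and the red cell and oxidative phosphorylation medians were 0.26 and -0.37. Red cell, oxidative phosphorylation and TGF-beta and BMP lists also lost their calls without wild-type replicate 2 (0.681, median -0.03; 0.564, median -0.03; 0.503) or heterozygous replicate 2 (0.127, 0.251, and 0.474 with a median of 0.23). Without either homozygous array oxidative phosphorylation and TGF-beta and BMP did not pass (0.118 each).

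**Figure D5:**
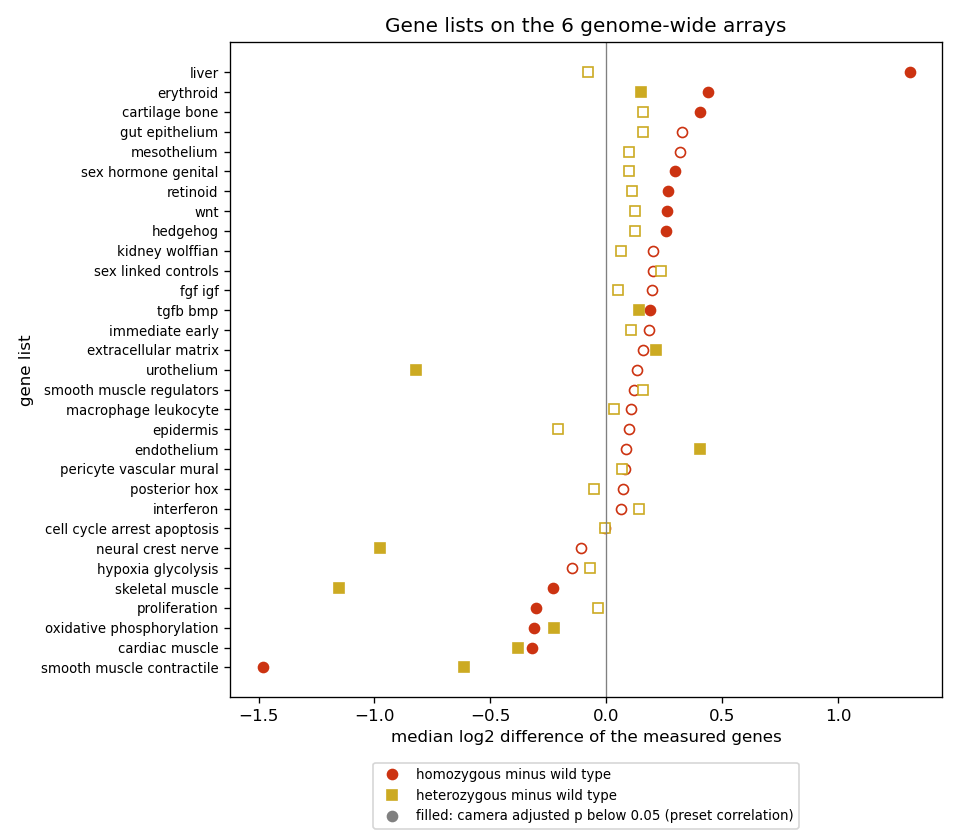
Median log2 difference from wild type (x axis) of the measured genes of each of the 31 lists (y axis) on the 6 genome-wide arrays labelled whole embryo, for homozygotes (circles) and heterozygotes (squares), n = 2 arrays per genotype; filled symbols have a camera adjusted p below 0.05 at the preset correlation. Smooth muscle contractile genes lie lowest in homozygotes (-1.48) and liver genes highest (1.31).

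No single gene of 20501 passed limma on these arrays: 0 in each comparison, with 1151 at an unadjusted p under 0.05 between homozygotes and wild type, 1191 between heterozygotes and wild type and 1366 between homozygotes and heterozygotes, where chance would give 1025. The smallest adjusted p were 0.0741, 0.391 and 0.493. A filter on the median level called 33, 14 and 5 genes, and an intensity trend with robust moderation 54, 13 and 6. Single arrays moved the counts: between homozygotes and wild type they were 111 without homozygous replicate 1, 37 without homozygous replicate 2 and 35 without either heterozygous array. Between heterozygotes and wild type they were 139 without either homozygous array and 1, Acta1, without heterozygous replicate 1, and between homozygotes and heterozygotes 53 and 43 without homozygous replicates 1 and 2 and 22 without heterozygous replicate 2.

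In whole embryos on the custom array Myocd differed by -0.18 (SE 0.11, adjusted p = 0.872) between homozygotes and wild type and by -0.11 in heterozygotes. All 3 male arrays held 4.94. These values average the females with a male difference fixed at 0, so they are smaller than the differences between the females. The perinatal and embryonic skeletal myosin genes Myh8 and Myh3 differed by 0.53 and 0.36 in homozygotes, and 2 of 3 skeletal muscle genes rose adjusted over the list alone. Of the contractile genes 1 of 4 fell adjusted over the list alone, Mylk at -0.18. No gene passed limma in any comparison: 0 each, with 109, 104 and 114 at an unadjusted p under 0.05 where chance would give 109. Collapsed values on these arrays hide differences. With median centring 2 genes passed between homozygotes and wild type, Ccdc50 and D16Bwg1543e.

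Bladders were compared with whole embryos on the custom array. Myocd lay 5.87 higher in bladder (SE 0.36), at 11.40 ± 1.00 (n = 24) against 5.66 ± 0.80 (n = 6). Of the contractile genes 3 of 4 rose, Mylk by 3.31 (SE 0.11), Kcnmb1 by 2.76 (SE 0.35) and Myh11 by 2.51 (SE 0.36), while Smtn differed by -0.12 (adjusted p = 0.746), a sign that turned to 0.40 with quantile normalization and 0.81 with median centring. Red cell genes fell, 3 of 3, with Slc4a1 at -4.24, Hba-x at -3.98 and Hba-a1 at -2.74, as did skeletal muscle genes, 3 of 3, with Myh8 at -6.75, Myh3 at -5.88 and Myl4 at -1.82. The liver gene Ahsg fell by 6.89 and the neuronal genes Mapt and Gap43 by 4.55 and 2.18. Among urothelium genes Upk1b rose by 1.91, Cldn7 by 1.14 and Krt19 by 0.64, while Krt14, a keratin of stratified epithelia, fell by 3.62; the list's median of 0.53 and mean of -0.04 differ in sign, and camera did not call it (adjusted p = 0.387). Extracellular matrix genes rose in 4 of 5 cases (median 0.56, camera adjusted p = 0.0108; adjusted p = 0.202 with an estimated correlation), with Mfap4 at 2.47 and Sparc at 1.03.

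In all 1681 genes passed, 460 higher and 1221 lower in bladder. The split depended on the scaling, at 782 and 766 with quantile normalization and 1014 and 571 with median centring. The median difference of all genes was -0.59 as deposited, 0.03 with quantile normalization and 0.34 with median centring, so differences near these sizes have no settled sign. Apart from Smtn, the genes named here kept their sign under each. Bladders and whole embryos also differed in RNA extraction, in the range of embryo numbers and in the collapsed values. The effect of tissue cannot be told apart from these.

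The effect of genotype was set between tissues on the custom array. Between bladder and whole embryo the homozygous difference of Sh3bgr differed by -3.62 (SE 0.71), with a bladder difference of -3.70 against -0.07 in whole embryos. It was the smallest adjusted p, at 0.0556, and limma called 0 genes, with 25 at an unadjusted p under 0.05. Sh3bgr alone passed without bladder homozygous replicate 3, 6 or 8 or wild-type replicate 3 (count 1), and Sh3bgr and Aoc3 passed without homozygous replicate 4 or wild-type replicate 4 (count 2). Ccdc50 differed between the tissues by -0.14 (SE 0.44, unadjusted p by limma 0.76).

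Across the 2183 genes of the custom array, which are not independent replicates, homozygous differences in bladder correlated with those on the arrays labelled whole embryo (r = 0.435, rho = 0.283), and 52 of the 55 called genes had the same sign there. All 6 of those embryo numbers are also numbers of bladders. With these 6 bladders left out, 18 bladders gave r = 0.357 and rho = 0.272, and 58 of 63 called genes had the same sign. Against whole embryos on the custom array the correlation was 0.123, with 38 of the 55 of the same sign, and between both embryo sets it was 0.071.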

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

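Chosen after the results were seen were the tests of mislabelled tissue and collapsed values on the genome-wide arrays and those of the Ccdc50 and Hoxb patterns, including the block of 3 ranges and the restriction of the neighbouring probe sets to the brighter ones; the splits of the arrays were planned, and those within the ranges were added after.

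Single bladder arrays stood apart from the others of their group in 4 of 48 groups of values tested over 24 named genes, where chance would give 2.4. Dlx3 was 7.98 in wild-type replicate 3, against 5.72 to 6.55 in the others. Myl4 was 10.47 in wild-type replicate 4, against 11.55 to 12.14, and 10.79 in heterozygous replicate 6, against 8.24 to 9.20. Slfn5 was 3.15 in heterozygous replicate 7, against 4.19 to 4.70.

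The homozygous minus wild-type difference differed between bladder and whole embryo for 9 named genes, adjusted over the 24 named genes alone, but 3 of them, Gabrb2 (1.66), Kcnmb1 (-2.66) and Slc2a4 (-1.58), held a single value on all whole-embryo arrays of 1 sex and are set aside. Over all genes limma called 0, with 25 at an unadjusted p under 0.05. Adjusted over the 14 named genes without such collapsed values, chosen after the data were seen, the other 6 passed. The bladder difference less that in whole embryos was -3.62 for Sh3bgr (adjusted p = 3.56e-04 by limma), -3.05 for Popdc2 (0.016), -2.77 for Myl4 (0.0036), -2.57 for Trpv2 (0.0083), -2.53 for Myl7 (0.0028) and -2.49 for Aoc3 (7.60e-04). These genes were named because they differed in bladder. A probe set without a gene name, which entered no gene test, was higher in homozygous bladders by 1.82 (SE 0.465, adjusted p = 0.0385 by limma; 3.59 ± 0.96 in 6 wild-type and 5.63 ± 1.54 in 11 homozygous arrays), with 0.10 in heterozygotes.

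The 6 genome-wide arrays labelled whole embryo resembled bladders. If these samples held bladder RNA, each would correlate better with every bladder than with any whole embryo, and 6 of 6 did. The collapsed values of the other whole embryos do not account for it: over the 1978 shared probe sets without such values the smallest gap between the lowest correlation with a bladder and the highest with a whole embryo was 0.0867. A mislabelled tissue is a candidate explanation, written as a hypothesis because it was found and tested on the same arrays. Dissection of another region rich in bladder tissue was not tested.

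Means of Ccdc50 and D16Bwg1543e were higher with more mgb alleles in bladders and in both sets labelled whole embryo. In bladder the step from heterozygotes to homozygotes passed for neither gene (adjusted p = 0.643 and 0.997 by limma). A difference between collection ranges is argued against by the block of 3 ranges, where the larger adjusted p by limma was 1.40e-04, and a lower share of smooth muscle by the whole embryos on the custom array, where the smallest difference in either sex was 1.41 for the brightest probe set of each gene and 1.31 over all 4. For gain of a wider segment, 3 neighbouring probe sets with a level above 5 were read. Their median difference was -0.12 (SD 0.10), below the lowest of the 4 probe sets of both genes (0.63), which argues against a gain that reaches them. The median of all 13 neighbours was -0.04 in bladder. A dim Fgf12 probe set lay at 0.97 there (SE 0.35, adjusted p = 0.213 by limma). An Il1rap probe set lay at -0.14 there but at 0.93 (SE 0.23) in whole embryos on the custom array. Besides the pair no probe set was read between positions 25516278 and 26942002, so a gain within that stretch was not tested. Among brighter probe sets a run of 10 genes from St6gal1 to D16Bwg1543e had a mean of 0.59 in bladder (permutation p = 0.006). Over all genes the best run ended at Bcl6 (permutation p = 0.400, and 0.391 and 0.447 at other offsets). The members nearest the pair were not above 0, Cldn1 at -0.12 (SE 0.21) and P3h2 at -0.20 (SE 0.19). On the arrays labelled whole embryo the run was of 28 genes from Ahsg to Fgf12 (mean 0.48, permutation p = 0.0599), with Cldn1 at 0.53. With a lower score offset it was 32 genes from C79999 to Fgf12 (mean 0.44, permutation p = 0.006). It was not found with a higher offset or among brighter probe sets. A difference between the genotypes stays open, and the genome at these genes was not tested.

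The run of 8 Hoxb genes was higher in homozygous bladders by a mean of 0.90. With 3 ranges as a block the mean was 0.73 (permutation p = 0.004), with 1.497 in the lower ranges and 0.34 in the higher range. The permutation shuffled gene positions, so its p measures how closely high values sit together and not the spread between embryos. It therefore cannot decide whether collection ranges are the cause. Hoxb3 on its own differed by 1.26 with the block (adjusted p = 0.0188 by limma). Nephric duct tissue carried along in the dissection was weighed as a source, and 2 of 3 duct genes were above 0, Lhx1 at 1.33 and Wnt9b at 1.20. None of these 3 passed limma over all genes, so this explanation cannot be told apart from a change within the bladder with 3 genes. A biological difference between the genotypes stays open and was not tested otherwise.

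Other splits of the bladders were set against the real genotypes. Between homozygotes and wild type 2 of 100 splits gave as many genes, the real one included (real 55, highest other 122), so chance is excluded at 0.05 for splits that disregard the ranges. The 122-gene split dealt 5 of 6 wild-type labels to the higher range and 8 of 11 homozygous labels to the lower ranges, a structure of the samples by range; with blocks the real count was 95 with 2 ranges and 76 with 3 ranges. The count was also 2 of 100 for heterozygotes against wild type (real 2, highest other 35, the same deal). It was 2 of 100 for homozygotes against heterozygotes as well (real 4, highest other 19, with all 7 heterozygous labels in the lower ranges). The allele trend gave 2 of 100 too (real 61, highest other 78), with the same reading as homozygotes against wild type. For the 2 pairs with heterozygotes the splits cannot exclude chance. All 3 genotypes were dealt at once, which mixed homozygotes into the groups compared. With genotypes dealt only within the 3 ranges, and the ranges as a block, 1 of 100 splits, the real one, gave as many genes in each of these comparisons. Chance is thus excluded at 0.05 for homozygotes against wild type and for the trend. For the 2 pairs with heterozygotes the same limit holds, and chance is not excluded. The real and highest other counts were 76 and 1 for homozygotes against wild type, 10 and 5 for heterozygotes against wild type, 6 and 5 for homozygotes against heterozygotes and 81 and 1 for the trend. For bladder against whole embryo it was 1 of 100 (real 1681, highest other 1220). For sex (highest other 754), sex by genotype (highest other 2) and tissue by genotype (highest other 973) the real count was 0, which all 100 splits reach, so the splits say nothing about chance there. The 754-gene split dealt 11 of 13 female labels to the lower ranges and 7 of 11 male labels to the higher range.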

How the results depend on the processing

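The block of 3 ranges and the removal of collapsed values were chosen after the data were seen. Of the counts and set tests, 311 values under alternatives stayed within 1.5 times or on the same side of the threshold and 68 moved; of the named genes' values between genotypes 2761 were the same, 132 gained and 140 lost a call, and 19 changed sign, where changes by less than 1 SE without a call count as the same. The causes of these changes were not tested; parts of the bladders hold fewer arrays, yet the lower ranges alone gave more calls than all bladders. No paired analysis was possible because the groups compared share no embryo numbers on 1 array type. Not run were a pseudocount, since values are log2, a random block of embryo numbers, a detection filter, since no calls are given, and the 6 columns that fit several samples. Dim probe sets carry no background value, which limits the small differences.

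Between homozygous and wild-type bladders (55) the count was 95 with 2 ranges as a block, 111 in the lower ranges, 10 in the higher range, 13 in females and 9 in males. For heterozygotes against wild type (2) it was 4 with median centring, 4 above the median level, 4 with 2 ranges and 10 with 3 ranges as a block, 1 in the lower ranges and 0 in the higher range, in females and in males by limma. For homozygotes against heterozygotes (4) it was 1 above the median level, 10 in the lower ranges, 0 in the higher range, 0 in females and 2 in males. The trend (61) gave 120 with 2 ranges. On the arrays labelled whole embryo (0 each) a filter gave 33, 14 and 5 and an intensity trend 54, 13 and 6; on the custom array of whole embryos (0) median centring and removal of collapsed values both gave 2. Bladder against whole embryo (1681) gave 824 above the median level, 3068 for every probe set and 911 without collapsed values. Tissue by genotype (0) gave 1, Sh3bgr, with quantile normalization, median centring, the filter, an intensity trend, no sex covariate and without collapsed values. Lists passing camera were 0 with an estimated correlation, against 1, 13 and 10.

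Without single arrays the counts were 28 to 80 (homozygous against wild-type bladders), 2 to 5 (heterozygous against wild type), 0 to 6 (homozygous against heterozygous), 33 to 88 (trend), 0 to 0 (sex), 0 to 4 (sex by genotype), 1623 to 1689 (bladder against whole embryo) and 0 to 2 (tissue by genotype). They were 0 to 111, 0 to 139 and 0 to 53 on the arrays labelled whole embryo and 0 throughout in whole embryos on the custom array, where the lone sample left is assumed to vary like the other groups.

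Between genotypes signs turned in the higher range for Gap43 (-0.42) and, in heterozygotes, Myocd (0.037). They also turned there for genes not followed in that comparison, which the count of sign changes above leaves out. Between heterozygotes and wild type these were Dlx3 (-0.59), Etv4 (-0.14) and Hoxb3 (-0.0295), and between homozygotes and heterozygotes Parp9 (-0.11) and Myl4 (0.41). Over removals of single arrays, on those labelled whole embryo, uncalled homozygous differences ran from -0.24 to 1.47 (Ocln), -0.20 to 1.63 (Hoxb13), -0.11 to 0.83 (Isl1), -0.76 to 0.0032 (Eng), -0.0297 to 0.83 (Anpep), -0.89 to 0.0485 (Cd14), -0.0495 to 1.53 (Cdx2), -1.32 to 0.29 (Ivl), -0.0677 to 0.71 (Muc16), -0.50 to 1.21 (Lrrn4), -1.38 to 0.071 (Plk1), -0.84 to 0.0355 (Ifi27), -0.0422 to 1.71 (Uty), -0.85 to 0.17 (Ddx3y) and -0.15 to 0.83 (Kdm5d). In whole embryos on the custom array Myocd ran from -0.25 to 0.0347 between heterozygotes and wild type and from -0.19 to 0.0538 between homozygotes and heterozygotes.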

Other observations

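The embryo numbers of the 6 genome-wide arrays are also numbers of bladders, with the same genotype and sex in both labels. The mean residual correlation was 0.238 for pairs of the same number and -0.048 for pairs of different numbers. Of the 6 arrays, 3 were closest to the bladder of their own number, among the 6 bladders with these numbers. Each of these numbers had a different combination of genotype and sex, so pairs of the same number were also the only pairs alike in both. These values therefore cannot tell a shared embryo from a shared genotype and sex. Whether the arrays and the bladders come from the same embryos could not be decided. The series text gives 7 wild-type bladders, while 6 were deposited with that label.

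On the genome-wide arrays labelled whole embryo, the heterozygous male array had lower uroplakins than the 5 others: 4.02 for Upk1a against 7.40 to 8.07, 4.89 for Upk2 against 6.79 to 7.82, and 5.42 for Upk3a against 6.99 to 7.70. Alb, which encodes albumin, ranged from 2.653 to 8.28 and was highest in the homozygous pair, at 8.28 and 7.16. Both were chosen after their values were seen.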
